A study of Mus musculus with 6 samples.

How the data were processed

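RNA sequencing counts from 6 libraries of EL4 cells were used, 3 from cells given vehicle and 3 from cells given 10 µM RGFP966 for 24 h. The deposited table holds raw read counts, 1 count column per library, for 51912 Ensembl mouse gene IDs. The values are whole numbers, no ID is duplicated, and 0 lines name anything other than a gene. Per the submitters' processing notes, the tools were CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0, and the genome build was mm10. Those notes give no role or order for the tools, so which aligner made the counts, the annotation release and the strand setting are not given in the sources used here. Per the labels, the samples are EL4 cells, while the submitters' extraction text speaks of retinas. A list of retina markers was therefore among the lists fixed.

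Symbols came from a table of gene names that covers 51633 of the IDs (99.46%). Positions, exonic length, GC content and exon overlaps came from GENCODE M21, on the same assembly as mm10, which holds 51719 of the IDs. Coordinates count from 1. Sequence shared between named genes and other annotated genes was measured as the percentage of a gene's 50-base exonic words that also occur elsewhere in annotated exons. Read length is not given in the sources used here, so this share approximates the sequence open to shared reads.

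Library totals ran from 12935443 to 16451017 counts. Polymerase chain reaction duplicates cannot be told from separate molecules in these counts, so the intervals given here cover counting error alone.

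The comparison was fitted in edgeR 4.0.16 with R 4.3.3, on the counts of all 6 libraries, with group as the only term. Genes of low count were removed with filterByExpr at its defaults. Libraries were scaled by trimmed mean of M values factors, and the robust quasi-likelihood F test was used. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are RGFP966 over vehicle on the log2 scale. Their standard errors (SE) were derived from the test, as the absolute log2 fold change over the square root of the F statistic. Levels are CPM from edgeR, which relate each count to its scaled library total, given as the mean of 3 libraries with the standard deviation (SD). Medians of marker lists with their 1 CPM minimum, sums of receptor genes and the rises in the MHC class II test use CPM of unscaled library totals instead. Measures of a whole library were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

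Gene lists, 43 in all, were fixed before the data were examined, as were the test, the rule for naming genes and most alternatives. The 37 lists with at least 5 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Its p-values were adjusted over those 37 lists. The lists covered the HDAC family with the NCoR corepressor complex, S-phase and replication, mitosis, CDK inhibitors and p53 targets, and pro-apoptotic and anti-apoptotic genes. They also covered MHC class I and class II antigen presentation, interferon-stimulated genes, immune checkpoints and their ligands, the T cell receptor complex, T cell transcription factors, T cell activation, cytokines and chemokines, cytotoxic genes, and T cell trafficking and adhesion. Others held NF-kB pathway genes, MYC and ribosome biogenesis, Notch, cholesterol biosynthesis, cholesterol efflux, fatty acid synthesis, fatty acid oxidation, glycolysis and hypoxia, and oxidative phosphorylation. The rest held the integrated stress response, the unfolded protein response, heat shock, autophagy and lysosome, antioxidant, DNA repair, histone, chromatin modifier, neuronal, circadian and solute carrier genes. Markers of retina, B cells, macrophages and myeloid cells, fibroblasts, erythroid cells, epithelium and endothelium made up the last 7.

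Genes were chosen for naming by a fixed rule. It took Hdac3 and the other tested HDAC genes, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap. Predicted genes and those with no symbol were counted but not named. From each list that was called or had at least 5 called members, it took 2 to 4 members of smallest adjusted p in the main direction and up to 2 in the other. It also took Cd274, H2-K1, B2m, Myc, Cdkn1a, Bcl2, Bcl2l11 and H1f0, whatever their result, and the 5 genes of smallest p. Results of some genes that the rule takes are not reported here. Any other gene named is said to have been chosen after its values were seen.

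Alternatives fixed with the design were a block for the replicate number, DESeq2 1.42.0 size factors, upper-quartile factors, total count alone, no filter, a minimum mean of 5 CPM, and removal of the 10 most abundant genes. The DESeq2 Wald test, limma-voom, glmTreat against 1.5-fold, camera with an estimated correlation, fry, and the removal of each library in turn were fixed too. Camera with an estimated correlation takes its degrees of freedom from the libraries rather than the genes, which raises its p-values even where the correlation is low. Chosen after seeing the data were the thinning of all libraries to the lowest total, offsets per library from splines on GC content and exonic length, and a scan of gene families. The offsets were first run as fitted, and the centring of each library's offsets on their median was chosen after seeing that result. Both forms are reported.

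The procedure was tested on simulated counts of 3 against 3 libraries with known changes. Of the changed genes it recovered 68% of 50 at 1.25-fold, 73.5% of 49 at 1.5-fold, 90% of 50 at 2-fold and 100% of 50 at 3-fold. Among its 174 calls 9 were false (5.17%). A simulated list of 20 genes raised 1.3-fold was found, and 0 lists without a simulated change were called. Genes were simulated independently of each other, and the unchanged lists held random genes. This therefore could not test the preset correlation between genes. The offsets brought a simulated GC slope of 0.0501 down to 0.00107, and calls made by that slope alone went from 6977 to 3.

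The counts were analysed at gene level, and neither reads nor transcript isoforms were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.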

Results

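Gene expression was measured by RNA sequencing in EL4 cells, a mouse T-cell lymphoma line, given vehicle or RGFP966, an inhibitor of the histone deacetylase HDAC3, at 10 µM for 24 h. Each group had 3 libraries. Vehicle libraries 1 to 3 held 15380331, 16451017 and 15773700 counts, and RGFP966 libraries 1 to 3 held 13564289, 12935443 and 14768540, a mean 13.3% lower (two-sided exact permutation p = 0.1, the smallest possible with n = 3 per group). On average 20052 genes had a count in vehicle and 19963 in RGFP966 libraries (two-sided exact permutation p = 0.7, n = 3). Ribosomal protein genes took 5.51% ± 0.223 (SD, n = 3) of counts in vehicle and 5.13% ± 0.114 in RGFP966 libraries (two-sided exact permutation p = 0.1). Long noncoding RNAs took 1.12% and 1.26% (two-sided exact permutation p = 0.1, n = 3), and genes of the mitochondrial genome 3.06% and 2.97% (two-sided exact permutation p = 0.6, n = 3). The first principal component held 40.1% of the variance, with vehicle libraries between -18.1 and -14.9 and RGFP966 libraries between 15.9 and 18.5. The labels do not say whether the libraries of a group came from separate cultures. Counts of libraries of 1 group differed by 2.15 to 3.33 times what counting error allows (chi-square per degree of freedom), so none was a copy of another.

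The comparison asked which genes differ in EL4 cells after exposure to the HDAC3 inhibitor. Lgmn, which encodes the lysosomal protease legumain, had the largest rise among genes chosen by size, from 2.85 ± 0.476 (SD, n = 3) to 13.4 ± 1.66 CPM. Gzma, which encodes the cytotoxic granule protease granzyme A, rose from 11.8 ± 0.944 to 39.6 ± 3.92 CPM. Pou2af1, a coactivator of octamer-binding transcription factors, rose from 202 ± 5.19 to 319.8 ± 11.2 CPM. Tfeb, a transcription factor for lysosomal genes, fell from 41.3 ± 1.78 to 25.6 ± 2.64 CPM. In every gene named as having risen or fallen, all 3 RGFP966 libraries lay on the same side of all 3 vehicle libraries. The rule for naming required this of the largest rises and falls, and it held for 2990 of all 3145 called genes. Of 13484 genes tested, 1543 were higher and 1602 lower with RGFP966 at an adjusted p under 0.05, which is 23.3% of the genes. The median change of the called genes was a rise of 24.8% and a fall of -14.0%. At 2-fold or more, 141 genes were higher, 33 of them predicted genes, and 14 were lower, 4 of them predicted. Those counts were 72 and 1 in the DESeq2 Wald test, 20 and 0 at a minimum of 5 CPM, and 136 and 8 after thinning to the lowest total. With no 2-fold cut, glmTreat called 45 genes higher and 0 lower against 1.5-fold. Groups did not overlap in 36.3% of the tested genes, where chance gives 10%. The balance of directions moved with the scaling: 49.1% of the calls were rises, against 59.1% with upper-quartile factors (1838 higher, 1270 lower) and 32.3% with offsets for GC content and length that were not centred (1213 higher, 2546 lower). It also differed with level. Between a mean of 2 and 5 CPM 147 genes were higher and 26 lower, and above 100 CPM 354 were higher and 583 lower. The median log2 fold changes of all tested genes at those levels were 0.09 and -0.03. Whether this trend with level bears on the calls of gene lists was not tested.

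**Figure D1:**
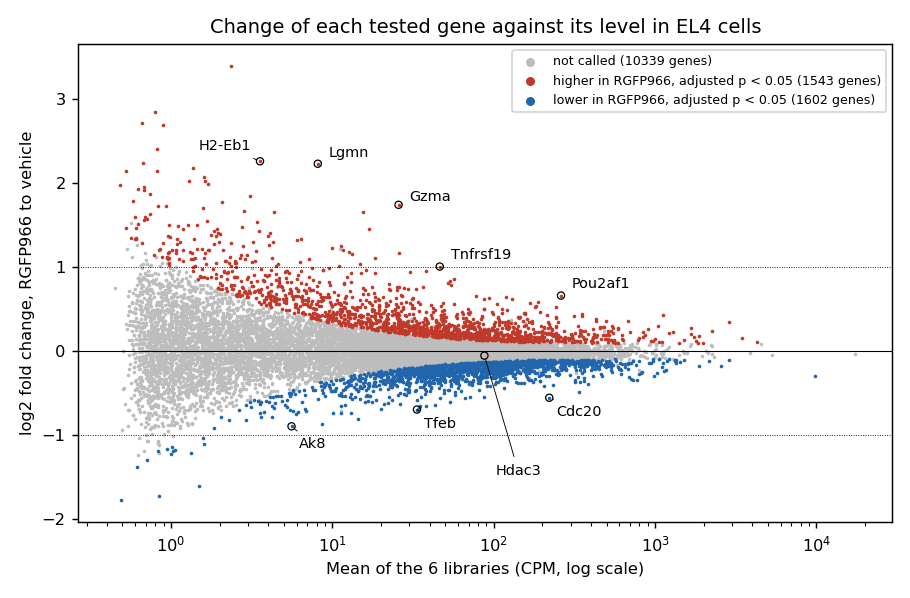
Each point is a gene tested, placed by its mean level over the 6 libraries (CPM, log axis) and its log2 fold change of RGFP966 over vehicle, with dotted lines at 2-fold; red marks the 1543 higher genes, blue the 1602 lower genes and grey the genes not called. Changes of at least 2-fold lie mostly at low levels, with 123 of the 141 rises and all 14 falls at a mean under 5 CPM.

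Among the 10 largest rises, Lgmn (on chromosome 12, 102394084 to 102439813, minus strand, ENSMUSG00000021190) had a log2 fold change of 2.23 ± 0.16 (SE, adjusted p = 6.77e-16). Gzma (chromosome 13, 113093825 to 113100981, minus strand, ENSMUSG00000023132) had the smallest p of all, with a log2 fold change of 1.74 ± 0.09 (adjusted p = 5.04e-21). Tbx19, a T-box transcription factor of pituitary cells, followed at 1.45 ± 0.11 (adjusted p = 8.87e-15), from 9.08 to 24.7 CPM. The other 7 lay between 1.34 and 1.15: Prokr1, a prokineticin receptor; Gli1, a transcription factor of Hedgehog signalling; Gimap8, a GTPase of lymphocytes; Il18rap, a subunit of the interleukin-18 receptor; Syt11, a synaptotagmin; Scel; and Tg, which encodes thyroglobulin. Pou2af1 (chromosome 9, 51213708 to 51240080, plus strand, ENSMUSG00000032053) changed by 0.66 ± 0.04 (adjusted p = 1.18e-18). The TNF receptor family member Tnfrsf19 rose by 1.01 ± 0.06 (adjusted p = 1.69e-17), from 30.8 to 61.8 CPM. Dntt, the polymerase that adds untemplated nucleotides during antigen receptor rearrangement, rose by 0.85 ± 0.06 (adjusted p = 1.30e-16), and Enpp1, an ectonucleotide pyrophosphatase, by 0.64 ± 0.04 (adjusted p = 2.41e-16).

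The largest falls were smaller than the largest rises. Ak8, an adenylate kinase, had a log2 fold change of -0.89 ± 0.17 (SE, adjusted p = 7.58e-05), from 7.24 to 3.92 CPM. Tfeb (chromosome 17, 47737030 to 47792419, plus strand, ENSMUSG00000023990) had one of -0.69 ± 0.07 (adjusted p = 3.00e-10), and the NF-kB subunit gene Relb one of -0.71 (adjusted p = 3.35e-04). Between these lay Dok4, with 31.2% of its exons overlapped by Polr2c, Etv4, an ETS transcription factor, Ptpre, a tyrosine phosphatase, Elavl4, a neuronal RNA-binding protein, Magi2, Polm, a DNA polymerase, and Wdfy3, at -0.81 to -0.71. Among the 14 genes at least 2-fold lower, Cox6a2, a muscle form of a cytochrome c oxidase subunit chosen after its values were seen, went from 2.22 to 0.739 CPM.

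Hdac3 transcripts themselves showed no detectable difference. Hdac3 (chromosome 18, 37935844 to 37955016, minus strand, ENSMUSG00000024454) measured 89.1 ± 3.83 (SD, n = 3) CPM in vehicle and 85.9 ± 2.49 CPM in RGFP966 libraries, a log2 fold change of -0.05 ± 0.05 (SE, adjusted p = 0.482). The class IIa deacetylase gene Hdac9 rose from 57.9 ± 2.67 to 71.3 ± 3.82 CPM, a log2 fold change of 0.30 ± 0.06 (adjusted p = 3.59e-05). Tbl1x and Tbl1xr1, which encode subunits of the NCoR corepressor complex that binds HDAC3, rose by 0.34 (adjusted p = 3.97e-09) and 0.33 (adjusted p = 3.80e-06). Ncor1, a scaffold gene of the complex chosen after its values were seen, measured 0.01 and was not called. Of the 15 tested members of the HDAC and NCoR list, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, and the list was not called (adjusted p = 0.392, but 9.94e-03 with fry, in a range up to 0.599).

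The smaller differences of other HDAC genes did not pass the test in every setting. Hdac1 had a log2 fold change of 0.13 (adjusted p = 0.0103), and Hdac7 one of 0.14 (adjusted p = 0.0317). Of the Hdac1 sequence 58.7% is shared with other annotated genes, of which the predicted gene Gm10093 shares most. The adjusted p of Hdac1 was 0.0686 without vehicle library 1 (log2 fold change 0.11), 0.117 without RGFP966 library 2 (0.10) and 0.115 with offsets not centred (0.08), in a range from 2.19e-03 to 0.117 over its alternatives. That of Hdac7 was 0.142 without vehicle library 2 (0.11), 0.0523 without vehicle library 3 (0.15), 0.237 without RGFP966 library 3 (0.10) and 0.105 in the DESeq2 Wald test (0.14), in a range from 8.05e-04 to 0.237. Hdac8 measured 0.24 (adjusted p = 0.0698), with 0.0459 under upper-quartile factors and 0.0458 at a minimum of 5 CPM, in a range from 0.0458 to 0.216. Hdac5 measured -0.12 (adjusted p = 0.104), Hdac10 -0.14 (adjusted p = 0.195), Hdac4 -0.04 (adjusted p = 0.726; 22.4% of its exons overlapped by Gm26720), Hdac6 -0.03 (adjusted p = 0.822) and Hdac2 -0.01 (adjusted p = 0.886). Hdac11 was removed by the filter on low counts. The 1 member that was lower, Gps2, measured -0.17 (adjusted p = 0.0489) and kept its call in few settings: without vehicle library 1 or 3, or RGFP966 library 1 or 2, its adjusted p was 0.162, 0.0995, 0.112 and 0.234, in a range from 0.0341 to 0.234.

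**Figure D2:**
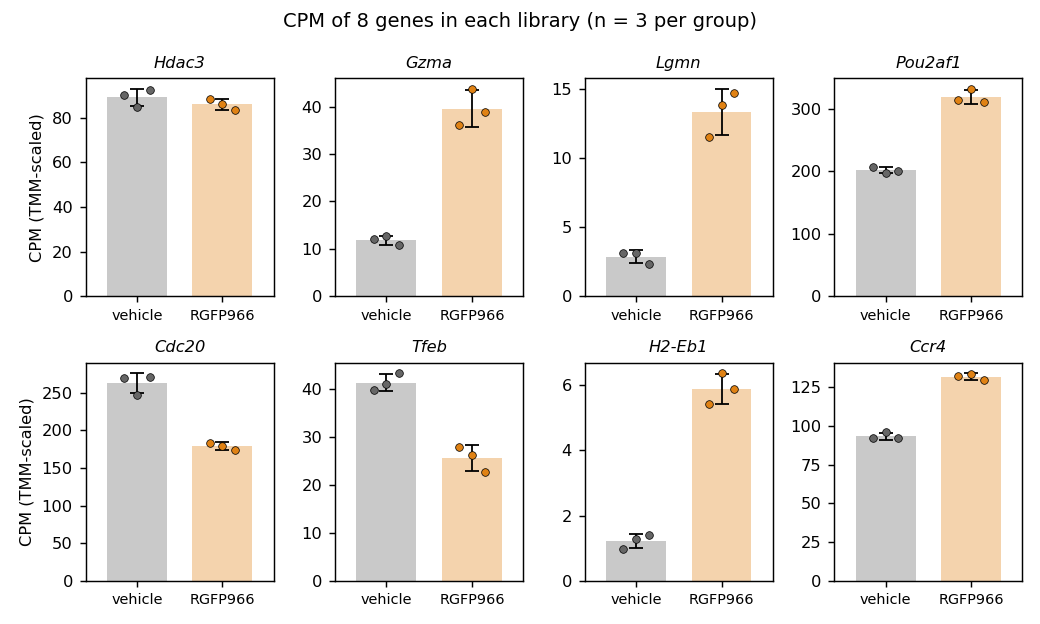
Levels of 8 genes in the 3 vehicle and the 3 RGFP966 libraries, in CPM after scaling; bars are means, whiskers standard deviations and points single libraries. In Gzma the RGFP966 mean is 39.6 CPM against 11.8 in vehicle, while the Hdac3 means are 85.9 and 89.1 CPM.

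Among T cell trafficking and adhesion genes, 8 of 15 tested rose. Ly6a, which encodes the surface antigen Sca-1, rose from 26.0 to 50.5 CPM (log2 fold change 0.95 ± 0.07 SE, adjusted p = 1.46e-15). Ccr4, a chemokine receptor gene, rose from 93.3 to 132 CPM (0.50 ± 0.04, adjusted p = 1.43e-12). Ly6c1, which shares 36.7% of its sequence with other genes, Ly6c2 most, rose by 1.67 from a level of 1.35 CPM (adjusted p = 4.55e-07). Of the others, 0 fell and 7 were not called by edgeR, with the same counts adjusted over the list alone. Cxcr4 and Ccr9, chemokine receptor genes chosen after their values were seen, measured -0.05 and -0.00. The list was called (median 0.50; adjusted p = 8.84e-04), with an adjusted p = 0.198 with an estimated correlation, the highest of its alternatives, which began at 1.59e-04.

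Among immune checkpoint genes and their ligands, 8 of 18 tested rose. Vsir, which encodes the checkpoint receptor VISTA, rose from 20.7 to 32.7 CPM (log2 fold change 0.66 ± 0.08 SE, adjusted p = 1.04e-08). Pdcd1, the gene of the receptor PD-1, rose by 0.23 (adjusted p = 1.18e-05) and the inhibitory receptor gene Btla by 0.26 (adjusted p = 2.64e-05). Cd274, the gene of the PD-1 ligand PD-L1, showed no detectable difference (0.00 ± 0.09; adjusted p = 0.991). By edgeR 0 checkpoint genes fell, with 10 rises and 0 falls adjusted over the list alone, and the list was called (median 0.25; adjusted p = 1.84e-03; adjusted p = 0.198 with an estimated correlation, in a range that began at 5.69e-04).

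In the T cell receptor list, Ptprc, which encodes the phosphatase CD45, rose from 648 to 756 CPM (log2 fold change 0.22 ± 0.04 SE, adjusted p = 2.34e-06), and Cd5, a receptor gene that restrains T cell receptor signals, rose by 0.28 (adjusted p = 3.29e-06). Lat, the gene of an adaptor of receptor signalling, fell by 0.22 (adjusted p = 5.80e-06). With 24 members tested, 9 rose and 3 fell, also when adjusted over the list alone, and the list was called (median 0.12; adjusted p = 0.0181; adjusted p = 0.244 with an estimated correlation, in a range that began at 9.52e-04). Among T cell transcription factors, the Ikaros family gene Ikzf3 rose from 147 to 213 CPM (0.53 ± 0.04; adjusted p = 5.38e-15), Id2 by 0.39 (adjusted p = 1.52e-07) and Zbtb7b, which directs the CD4 lineage, by 0.41 (adjusted p = 4.77e-07). Bcl11b, a factor of T cell commitment, fell by 0.18 (adjusted p = 9.77e-04). Of the 22 tested factors 9 rose and 1 fell, or 10 and 2 adjusted over the list alone, and the list was called (median 0.10; adjusted p = 0.0116; adjusted p = 0.599 with an estimated correlation). Without vehicle library 2 its median was 0.07 and its adjusted p 0.0911, in a range from 1.32e-03 to 0.599.

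Among MHC class II genes, 3 of 5 tested rose, all from low levels. H2-Eb1 (chromosome 17, 34305867 to 34316674, plus strand, ENSMUSG00000060586), which encodes a class II beta chain, went from 1.22 ± 0.221 (SD, n = 3) to 5.90 ± 0.461 CPM, a log2 fold change of 2.26 ± 0.23 (SE, adjusted p = 6.77e-11). Cd74, the gene of the invariant chain, rose by 1.3 (adjusted p = 1.28e-03). H2-DMb1, which shares 27.2% of its sequence with other genes, H2-DMb2 most, rose by 1.17 (adjusted p = 3.84e-03). By edgeR 0 members fell, with 4 rises and 0 falls adjusted over the list alone, and the list was called (median 1.17; adjusted p = 2.40e-03; adjusted p = 0.198 with an estimated correlation, in a range that began at 7.90e-05). MHC class I genes went both ways. H2-K1 rose by 0.22 (adjusted p = 2.07e-06), H2-D1 by 0.29 (adjusted p = 4.73e-09) and B2m, the gene of the shared light chain, by 0.27 (adjusted p = 5.50e-08), while the immunoproteasome subunit gene Psmb10 fell from 42.2 to 26.5 CPM (-0.67, adjusted p = 2.08e-10). H2-Q4 and H2-Q7, with 22% and 27.1% shared sequence, rose by 0.40 and 0.41. Of 22 tested class I genes 6 rose and 6 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.709); its median was 0.01, its mean -0.01 and its test upward.

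Among mitosis genes, 17 of 26 tested fell. Cdc20 (chromosome 4, 118432901 to 118437352, minus strand, ENSMUSG00000006398), an activator of the anaphase-promoting complex, went from 263 ± 13 (SD, n = 3) to 179 ± 5.09 CPM, a log2 fold change of -0.55 ± 0.04 (SE, adjusted p = 1.88e-15). The mitotic kinase gene Plk1 fell by 0.32 (adjusted p = 3.87e-07), the cyclin gene Ccnb2 by 0.28 (adjusted p = 2.90e-06) and the centromere protein gene Cenpf by 0.27 (adjusted p = 2.48e-06). The rest were 1 rise and 8 genes not called, with the same numbers of falls and rises adjusted over the list alone, and the list was called (median -0.16; adjusted p = 6.11e-06; adjusted p = 0.198 with an estimated correlation, in a range that began at 6.21e-07). The 1 higher member, the topoisomerase gene Top2a, measured 0.11 (adjusted p = 0.0135), but 0.0610 without vehicle library 1, 0.0676 without RGFP966 library 1, 0.0780 without RGFP966 library 2 and 0.416 with offsets not centred, in a range that began at 1.76e-03.

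Among S-phase and replication genes, 11 of 31 tested fell and 3 rose. Mcm4, the gene of a replicative helicase subunit, fell by 0.19 (adjusted p = 1.35e-04) and Rrm2, that of a ribonucleotide reductase subunit, by 0.18 (adjusted p = 2.66e-04), as did Mcm7 by 0.23 (adjusted p = 3.52e-06; 26.0% shared sequence), while Mcm3 rose by 0.14 (adjusted p = 2.23e-03). The counts were 12 and 3 adjusted over the list alone, and the list was called (median -0.09; adjusted p = 0.0181; adjusted p = 0.599 with an estimated correlation). Its adjusted p was 0.120 without RGFP966 library 3, with a median of -0.07, and 0.0680 at a minimum of 5 CPM, in a range from 4.10e-03 to 0.599.

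Among oxidative phosphorylation genes, 10 of 20 tested fell. Sdhb, a subunit gene of complex II, fell from 190.2 to 149.7 CPM (log2 fold change -0.35 ± 0.04 SE, adjusted p = 5.91e-09). Ndufa2, of complex I, fell by 0.39 (adjusted p = 9.26e-05) and Cox4i1, of complex IV, by 0.24 (adjusted p = 1.29e-05). By edgeR 0 members rose, with 12 falls and 0 rises adjusted over the list alone, and the list was called (median -0.11; adjusted p = 2.17e-03). Its adjusted p was 0.599 with an estimated correlation and 0.0679 with fry, in a range that began at 2.23e-04. Circadian clock genes, some of them targets of the complex of NCoR and HDAC3, were also called (median -0.18; adjusted p = 0.0393; adjusted p = 0.311 with an estimated correlation). Per1, a clock repressor gene, fell by 0.30 (adjusted p = 9.37e-04), and Arntl, which encodes the activator BMAL1, rose by 0.24 (adjusted p = 4.00e-03). Of 15 tested clock genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone. Several of the 5 falls lost their calls without vehicle library 1 (adjusted p of 0.0560 to 0.119) or without RGFP966 library 1 (0.0574 to 0.198). The list's call was lost without vehicle library 1 (median -0.14, adjusted p = 0.0519) and without RGFP966 library 3 (median -0.17, adjusted p = 0.0748). It was also lost at a minimum of 5 CPM (0.0838), after thinning (0.0779) and with offsets not centred (0.0716), in a range from 7.95e-03 to 0.311.

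**Figure D3:**
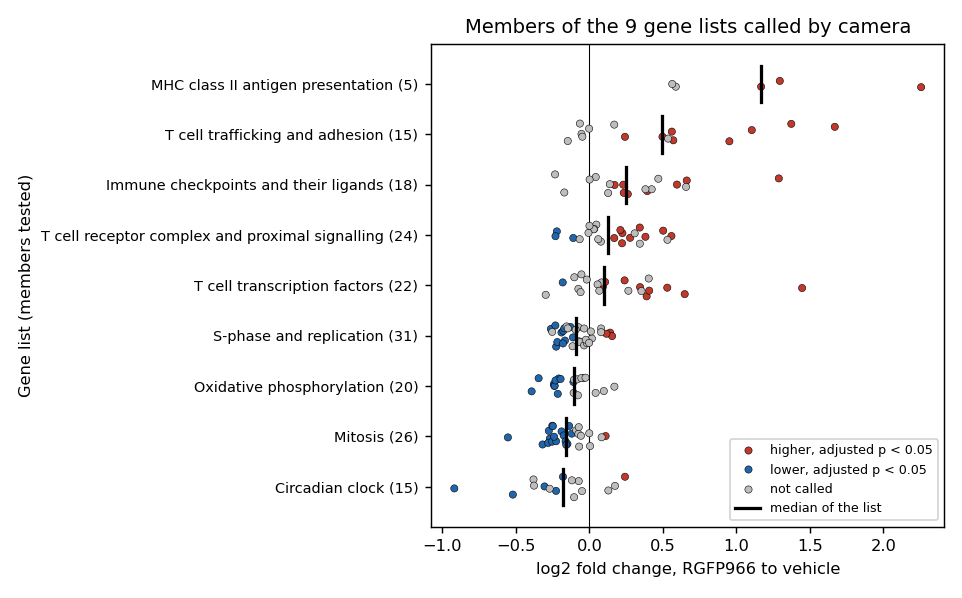
Log2 fold changes of RGFP966 over vehicle of the tested members (points) of the 9 called lists, 1 list per line; black bars mark list medians and the vertical spread within a line carries no value. The medians run from 1.17 for MHC class II genes to -0.18 for circadian clock genes.

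The other 28 lists tested were not called, and their counts adjusted over the list alone are given where they differed. With fry, which does not compare a list with other genes, the CDK inhibitor (adjusted p = 0.0219), cytotoxic (0.0132), fatty acid synthesis (0.0190), fatty acid oxidation (0.0143) and neuronal (0.0193) lists passed, each at the low end of a range up to 0.599 over its alternatives. Among CDK inhibitors and p53 targets 6 of 19 rose and 1 fell (7 and 3 adjusted over the list alone, adjusted p = 0.392). Cdkn1a, the gene of the inhibitor p21, rose from 55.3 to 72.8 CPM (log2 fold change 0.40; adjusted p = 1.20e-07), Cdkn2a rose by 2.07 from 0.609 CPM (adjusted p = 7.06e-06), and Cdkn2c fell by 0.29 (adjusted p = 6.96e-06). Among 12 pro-apoptotic genes 3 rose and 2 fell (4 and 3 adjusted over the list alone, adjusted p = 0.590). Bcl2l11, which encodes BIM, rose from 14.9 to 21 CPM (0.49, adjusted p = 7.83e-05), Tnfsf10, which encodes TRAIL, by 0.55 (adjusted p = 1.88e-05) and Bmf by 0.59 (adjusted p = 2.14e-03). Of 8 anti-apoptotic genes 1 fell and 0 rose by edgeR (adjusted p = 0.529), and Bcl2 showed no detectable difference (-0.00, adjusted p = 0.962).

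Interferon-stimulated genes had 4 rises and 1 fall among 32 tested (adjusted p = 0.444). Rsad2, an antiviral gene, rose by 1.06 (adjusted p = 2.40e-06) and Usp18, a negative regulator of interferon signalling, by 0.65 (adjusted p = 9.30e-06), while the nucleic acid sensor gene Zbp1 fell by 0.81 (adjusted p = 5.93e-03). Among 19 T cell activation genes 4 rose and 3 fell (5 and 4 adjusted over the list alone, adjusted p = 0.901), with the adhesion receptor gene Cd44 rising by 0.38 (adjusted p = 2.88e-10), Il2rg, with 42% shared sequence, by 0.42 (adjusted p = 3.71e-05), and Junb falling, at -0.27 (adjusted p = 6.85e-04). That list had a median of -0.09 with a mean of 0.02 and an upward test. Without RGFP966 library 1 some of its members lost their calls (adjusted p = 0.109 and 0.0952 among the rises and 0.112 among the falls). Of 8 cytotoxic genes 3 rose and 1 fell (adjusted p = 0.259; median -0.01, mean 0.34, test upward). Besides Gzma, Srgn, the gene of the granule proteoglycan serglycin, rose by 0.44 (adjusted p = 2.45e-11) and the granzyme gene Gzmb by 0.98 (adjusted p = 3.25e-04), both chosen after their values were seen. Of 12 NF-kB genes 4 fell and 0 rose by edgeR (5 and 0 adjusted over the list alone, adjusted p = 0.277), among them Relb and, chosen after its values were seen, Nfkb2, which fell by 0.49 (adjusted p = 5.53e-09). Cytokines and chemokines had 1 fall among 7 (adjusted p = 0.729). Of 6 Notch genes 3 rose (adjusted p = 0.133, but 0.0204 without RGFP966 library 2, in a range from 0.0204 to 0.599), including the target gene Hes1, chosen after its values were seen (1.93, adjusted p = 3.73e-03). The rises other than Hes1 lost their calls in several settings, among them without vehicle library 1 (adjusted p = 0.191 and 0.0574) and without RGFP966 library 3 (0.168 and 0.354).

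In the MYC and ribosome biogenesis list 8 of 27 genes fell and 3 rose (adjusted p = 0.423). Myc itself rose by 0.18 (adjusted p = 3.55e-04) and the nucleolar gene Nop56 by 0.16 (adjusted p = 9.32e-04), while Rrp9 and Utp20, of ribosomal RNA processing, fell by 0.23 (adjusted p = 2.56e-04) and 0.17 (adjusted p = 9.19e-04). Lipid genes went both ways. Among cholesterol biosynthesis genes 5 of 24 rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.837), with the sterol reductase gene Dhcr7 rising by 0.40 (adjusted p = 2.50e-10) and Cyp51 by 0.30 (adjusted p = 3.79e-09). Among fatty acid synthesis genes 6 of 14 rose and 2 fell (adjusted p = 0.194), with the desaturase gene Scd2 rising by 0.35 (adjusted p = 1.51e-11), the lipid droplet gene Plin2 by 0.26 (adjusted p = 2.76e-03), and Acly, of citrate cleavage, falling, at -0.21 (adjusted p = 1.18e-05). Fatty acid oxidation had 3 rises and 1 fall among 15 (adjusted p = 0.423), and cholesterol efflux 2 falls among 5 (adjusted p = 0.529). Glycolysis and hypoxia genes had 4 rises and 0 falls by edgeR among 24 (3 and 0 adjusted over the list alone, adjusted p = 0.529; median -0.02, mean 0.05, test upward), including the glucose transporter gene Slc2a3, chosen after its values were seen (0.20, adjusted p = 8.87e-06). Without vehicle library 1 that list had an adjusted p of 0.0268, in a range from 0.0268 to 0.973.

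Integrated stress response genes had 8 falls and 2 rises among 17 (9 and 2 adjusted over the list alone). The 1-carbon enzyme gene Mthfd2 fell by 0.24 (adjusted p = 7.05e-06), the serine synthesis gene Psat1 by 0.22 (adjusted p = 9.36e-06) and Trib3 by 0.52 (adjusted p = 8.11e-05), while Ddit4, an inhibitor of mTORC1 signalling, rose by 0.50 (adjusted p = 2.78e-06) and Atf3 by 2.14 from 0.293 CPM (adjusted p = 3.90e-04). The list missed its call (adjusted p = 0.0718; median -0.13, mean 0.02, test downward), which it passed at a minimum of 5 CPM (0.0154) and with fry (0.0170), in a range from 0.0154 to 0.571. Of 15 unfolded protein response genes 4 fell and 2 rose (adjusted p = 0.392), with Edem1 of protein quality control falling by 0.22 (adjusted p = 1.31e-04) and Creld2 by 0.25 (adjusted p = 1.07e-03). Of 10 heat shock genes 3 fell and 2 rose (adjusted p = 0.643), with the co-chaperone gene Dnajb1 falling by 0.21 (adjusted p = 6.44e-03) and Hsp90aa1, with 58.5% shared sequence, rising by 0.17 (adjusted p = 1.44e-04). The falls other than Dnajb1 lost their calls without vehicle library 3 (adjusted p = 0.0929 and 0.0511) and without RGFP966 library 3 (0.217 and 0.199). The rise other than Hsp90aa1 lost its call without RGFP966 library 1 (0.0749) or 2 (0.109). Of 18 autophagy and lysosome genes 3 rose and 3 fell (adjusted p = 0.709), with the membrane protein gene Lamp2 rising by 0.23 (adjusted p = 2.61e-05) and Tfeb among those falling. Of 14 antioxidant genes 5 fell and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 0.529), with Sod1 falling by 0.24 (adjusted p = 3.43e-05), Gpx4, with 61.7% shared sequence, by 0.33 (adjusted p = 3.80e-06), and the heme oxygenase gene Hmox1 rising by 0.24 (adjusted p = 1.76e-03).

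Among chromatin modifier genes 5 of 23 fell and 1 rose (adjusted p = 0.194). The acetyltransferase genes Kat2b and Kat2a fell by 0.40 (adjusted p = 4.55e-06) and 0.21 (adjusted p = 1.44e-04), and Hmgn2, a nucleosome-binding protein gene with 22.5% shared sequence, by 0.48 (adjusted p = 9.81e-14). Among 10 histone genes 2 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.729), and H1f0, the gene of linker histone H1.0, rose by 0.30 (adjusted p = 1.43e-07). Of 22 DNA repair genes 5 rose and 1 fell (adjusted p = 0.590). Parp1 rose by 0.13 (adjusted p = 5.69e-03) and Brca2 by 0.19 (adjusted p = 4.25e-03, but 0.0630 with offsets not centred, in a range that began at 1.38e-03). Of 8 neuronal genes 3 rose and 1 fell (adjusted p = 0.194), among them Syt11 and, chosen after its values were seen, the neuronal tubulin gene Tubb3, which rose by 0.53 (adjusted p = 2.19e-09). Solute carriers and drug efflux genes had 2 rises and 2 falls among 8 (2 and 3 adjusted over the list alone, adjusted p = 0.590), with the zinc transporter gene Slc39a10, chosen after its values were seen, falling by 0.65 (adjusted p = 6.37e-10).

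Most marker genes of other cell types had low levels in both groups. Median levels in vehicle and RGFP966 libraries were 0.0625 and 0.0999 CPM for retina, 0.263 and 0.422 for B cells, 0.0101 and 0.0461 for macrophages and myeloid cells, and 0.0217 and 0.151 for fibroblasts. They were 0.0106 and 0 CPM for erythroid cells, 0.0211 and 0 for epithelium, and 0.0311 and 0.0493 for endothelium. Of the 17 retina markers 4 reached a mean of 1 CPM, of which Thy1, also in the T cell receptor list, measured 894 and 944 CPM. Gnb1 of the same list, a G protein subunit gene, measured 398 and 428 CPM (log2 fold change 0.11, adjusted p = 0.0277). Its adjusted p was 0.0743 and 0.126 without vehicle libraries 1 and 2, 0.111 and 0.0755 without RGFP966 libraries 1 and 3, and 0.344 with offsets not centred, in a range that began at 5.33e-03. B cell markers had 5 tested members, 1 higher and 1 lower, and the list was not called (adjusted p = 0.787; median -0.05, mean 0.03, test upward). Cd22, a receptor gene of B cells, rose from 9.40 to 16.6 CPM (log2 fold change 0.82; adjusted p = 9.66e-08). Pdgfra of the fibroblast list rose from 44.3 to 54.1 CPM (0.29, adjusted p = 2.10e-04), and Pecam1 of the endothelium list from 51.7 to 62.1 CPM (0.26, adjusted p = 3.24e-04). Tek, also of the endothelium list, measured 3.76 and 5.56 CPM (0.56, adjusted p = 0.0181, but 0.0614 without vehicle library 3, 0.113 without RGFP966 library 1 and 0.0878 in the DESeq2 Wald test, in a range that began at 0.0145). Ighm, the gene of the IgM heavy chain, measured 539 and 498 CPM (-0.11, adjusted p = 0.0150, but 0.0532 without RGFP966 library 2, 0.0716 without RGFP966 library 3 and 0.0520 with upper-quartile factors, in a range that began at 1.30e-03). Thy1, Gnb1, Cd22, Pdgfra, Pecam1, Tek, Ighm and Lyz2 were chosen after their values were seen. Lyz2, the myeloid marker with the highest level, measured 8.27 and 7.87 CPM. The retina, myeloid, fibroblast, erythroid, epithelium and endothelium lists had fewer than 5 tested members and were not tested as lists.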

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

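Of the tests under other settings given here, the thinning to the lowest total and both forms of the GC and length offsets were chosen only after the results were seen. Of 165 genes chosen for naming, 156 were called. In the 17 settings with a test of each of them, 129 kept their call wherever no single library was removed, 125 also where one was, and 0 reversed, but 8 of the 165 had no value at a minimum of 5 CPM, and Atf3, 1 of the 8, had none in the DESeq2 Wald test either. Without the 10 most abundant genes, 150 of the 153 still tested were called, and glmTreat called 16 higher and 0 lower of the 156. Directions of uncalled results were not compared. Over the removals of single libraries, higher genes numbered 1238 to 1385, lower genes 1116 to 1484, those at least 2-fold higher 133 to 167 and lower 11 to 17, and called lists 7 to 10; with fewer libraries each test had fewer degrees of freedom. With a replicate block the fit called 1667 higher and 1764 lower genes, kept 3139 of the 3145 calls and changed no named gene or list call. Deviations of libraries with the same number correlated at -0.046, 0.158 and -0.0086 across genes, which are not independent, so the replicate numbers do not show a pairing. Among libraries with different numbers, vehicle 1 with RGFP966 3 correlated at 0.139 and vehicle 3 with RGFP966 1 at 0.0862, and the rest were negative. Whether libraries were paired under other numbers was not tested. At a minimum of 5 CPM, 20 genes were at least 2-fold higher and 0 lower by edgeR (0 also at an unadjusted p under 0.05), since fewer genes were tested. After thinning, 3025 genes were called, 2885 of them also called at full depth, and 8 were at least 2-fold lower. Offsets that were not centred gave 2546 lower genes, with the median of all genes moved by -0.0475, while the centred form moved no count by over 1.5 times. Both forms differ by a constant per library, so the uncentred one rescales the libraries on top of the scaling factors. The DESeq2 Wald test gave an adjusted p for 11796 genes, against 13484 in the main fit. It called 1011 higher genes, 72 at least 2-fold higher and 1 lower. For thinning and the Wald test the cause was not tested. Tested against 1.5-fold, glmTreat called 45 higher and 0 lower (29 lower at an unadjusted p under 0.05), as its construction asks for larger changes. With an estimated correlation camera called 0 lists (5 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 15. The estimates for the 9 called lists ran from -0.229 (MHC class II) to 0.397 (oxidative phosphorylation). Mitosis, at 0.0176, still went from a camera adjusted p of 6.11e-06 to 0.198. That form has few degrees of freedom here, so a call lost under it is not by itself a sign of correlation between genes.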

Other observations

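The scan of gene families with its ribosomal protein set, the MHC class II test, the thinning, the GC and length offsets and the receptor ratio without its 10 most counted genes were tests chosen only after the results were seen. In the scan of 335 families sharing a symbol stem, 7 were called by camera. The largest median of these 7 was that of the Gimap genes, GTPases of lymphocytes that lie together on chromosome 6 between 48647234 and 48754210: all 7 tested members rose, with a median log2 fold change of 0.74 (adjusted p = 4.00e-06). Gimap6 rose from 24.8 to 41.4 CPM and Gimap7 by 1.53 (adjusted p = 4.96e-07). The Rpl (49 genes, median -0.15; adjusted p = 1.02e-05) and Rps (44 genes, median -0.14; adjusted p = 2.47e-04) stems were lower, and 18 of their genes are paralogs, S6 kinases or a binding protein. Of the other 75, which are named as ribosomal proteins, 43 fell and 0 rose by edgeR (median -0.14, and -0.19 to -0.12 over the scalings run; camera p = 2.29e-11, p = 0.2995 with an estimated correlation). Many of them have pseudogene copies whose reads they can share. The Ndufb stem, of complex I (median -0.21; adjusted p = 0.0280), and the Cox stem, of cytochrome c oxidase subunits and assembly factors (median -0.15; adjusted p = 0.0385), were lower, and the Rtn (5 genes, median 0.22; adjusted p = 0.0280) and Rgs (15 genes, median 0.34; adjusted p = 0.0445) stems higher. Rtn4ip1 and Rtn4rl1 of the Rtn stem and Rgs9bp of the Rgs stem, chosen after their values were seen, share the stem but are named as other proteins, and none was called. None of the 7 called families was called by camera with an estimated correlation (adjusted p = 0.959 for each). With the few degrees of freedom of that form, this does not show that correlation between genes made the calls. The direction of none of the 7 medians turned under the scalings run.

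Changes of at least 2-fold were mostly rises, 141 against 14. Lower depth of the RGFP966 libraries is 1 candidate explanation, but with every library thinned to the lowest total rises still made up 94.4% of these calls. Genomic DNA or another uniform background is another: the summed level of 1701 olfactory and vomeronasal receptor genes, which T cells are not known to use, was 34.2 ± 0.531 (SD, n = 3) CPM in vehicle and 42.6 ± 3.21 CPM in RGFP966 libraries, a ratio of 1.245 (pooled 95% interval 1.17 to 1.34), short of 2-fold. Without the 10 most counted of these genes, which held 72.9% of the counts, the ratio was 1.05. A response of weakly expressed genes to the inhibitor remains open as a hypothesis that no separate test addressed.

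The oxidative phosphorylation and mitosis lists were called lower. A trend with GC content and gene length was weighed, since fold changes correlated weakly with both across genes (Spearman's rho -0.0948 and 0.0563, with genes not independent replicates). With centred offsets the median of the oxidative phosphorylation list was -0.12 against -0.11 without (adjusted p = 1.19e-03), and that of the mitosis list -0.17 against -0.16 (adjusted p = 6.21e-07). The trend therefore does not account for either call. With offsets not centred the medians were -0.17 (adjusted p = 1.61e-03) and -0.22 (adjusted p = 1.70e-06). That form differs from the centred one only by rescaling the libraries, so it is no second test of the trend. A change in growth rate with the inhibitor might lower both lists, and it was not tested here.

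The MHC class II list was called higher. Antigen-presenting cells of another type in the RGFP966 cultures could bring such transcripts, but they would bring H2-Aa and H2-Ab1 together with H2-Eb1. The summed rise of H2-Aa and H2-Ab1 was 0.165 CPM, with an upper 95% counting bound of 0.446 CPM on their RGFP966 level, against a rise of 4.70 CPM for H2-Eb1. H2-Ab1 had 0 counts in vehicle and 0 in RGFP966 libraries, and whether it could be counted here is not known. The test thus rests on H2-Aa alone, with 4 counts over the vehicle and 10 over the RGFP966 libraries. Ciita, the class II transactivator, had 4 counts over the vehicle and 2 over the RGFP966 libraries. A change within the EL4 cells remains open as a hypothesis.

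Other splits of the 6 libraries into 3 and 3 number 9, and with the real split the 10 are too few for a share under 0.05. The real split gave 3145 called genes, 155 of at least 2-fold and 9 called lists, and the highest of the other splits was 0 called genes by edgeR (394 at an unadjusted p under 0.05), 0 of at least 2-fold and 3 lists. In each case 1 split, the real one, reached the real value. Every other split puts vehicle and RGFP966 libraries together in both sets, so any group difference adds to the spread within its sets. Few calls are thus built into the other splits, and no conclusion is drawn from their counts.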
